A study of Mus musculus with 768 samples.

How the data were processed

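RNA of single mouse CD4 T cells was measured with Smart-seq2, a plate-based protocol that makes full-length cDNA from 1 cell per well. Each deposited sample is 1 well, labelled as a cell, and the 768 samples fall into 8 groups of 96 wells. The groups combine 2 culture conditions, 2 eGFP gates and 2 genotypes of a mouse line with an eGFP reporter in the Il23r locus. Control mice carry 1 reporter allele, and mice with the reporter on both alleles are the functional knockout (KO), per the series' design text.

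The deposited values are TPM, transcript abundances scaled to 1 fixed total per cell, 1 column per cell. The columns summed to between 999999 and 1000001, so the values keep no sequencing depth. Trimmomatic 0.32, Bowtie2 2.2.9, RSEM 1.2.31 and the mouse build GRCm38 are named in the submitters' processing notes, which give neither their roles nor their order. The annotation is not given in the sources used here. A deposited cell table covers the 384 Th1 cells and names 1 mouse for all control cells and another for all KO cells. The animals behind the Th17 cells are not given in the sources used here. All columns matched a labelled sample (0 columns not matched), and no 2 columns were identical.

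The table held 25125 rows with 23415 gene symbols. For the 1237 symbols on more than 1 row, 676 of which had identical rows, the TPM of the rows was added up within each cell. Of the symbols, 22911 (97.8%) matched a mouse gene of the RefSeq annotation of GRCm38, which also gave the coordinates. Cells with at least 1000 genes above 0 TPM were used, which left 755 of 768 wells. The 13 wells left out listed 13 to 70 genes, and 8 of them were the well numbered 73 of each plate. No doublet caller was run, since single cells were sorted into wells. The well numbered 85 listed the most genes on every plate and may hold more than 1 cell. It was kept and counts as 1 cell of its group, and an added alternative left it out.

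Each comparison is a difference of group means of log2(TPM + 1) over cells, for genes above 1 TPM in at least 25% of the cells of 1 of the 2 groups. A pseudocount understates differences of low genes. The animal or culture is the unit of replication, and each group holds 1 such unit in the Th1 cell table and an unknown number elsewhere. Each group was therefore treated as 1 sample, and no p-values, standard errors or numbers of changed genes were made from cells. SDs describe the spread between cells. A share is the percentage of used cells above 1 TPM. Its exact (Clopper-Pearson) 95% interval covers the counting error of cells and nothing else, and a share of 0 is given with the upper limit that 3 cells would set. The median number of genes per cell stands in for depth.

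Fixed lists of genes (30 lists and 23 key genes) were written from textbook knowledge, with marker lists of other cell types among them. A list was summarised by the median difference of its compared members, given relative to the median of all compared genes. Its percentile is its place among 10000 random lists of equal size, matched on mean expression in 20 bins, and describes these libraries alone. Lists share members: Ccr7 stands in those for naive and memory cells and for homing, and Il21 in those for Th17 cells and cytokines.

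Genes above the 25% limit were named by a fixed rule, which left out predicted genes and receptor segments. It takes the key genes, then for Th17 minus Th1 the 10 highest and 10 lowest by their smallest difference over the 4 pairs of plates, among genes with 1 sign in all 4. For KO minus control it takes the 5 highest and 5 lowest of the same kind. It adds the 10 highest and 10 lowest genes of each eGFP-positive pair and the 5 highest and 5 lowest of each eGFP-negative pair. For the gates it takes the 10 highest and 10 lowest in control cells of each condition, and for the KO difference between gates the 5 highest and 5 lowest. Last come up to 4 members of each described list, those with the largest differences. A few genes that the rule takes are not reported here. Groups, comparisons, filters, lists, most alternatives and this rule were set before the data were examined. The lists to be described with examples, the reporter transcript (deposited under the name EGFP_IRES_IL23R) among the shares, and 3 alternatives were chosen after seeing the data. The 3 added alternatives left out well 85 of each plate, took the highest row of each symbol, or left out cells with RNR2, the mitochondrial 16S ribosomal RNA, above 100000 TPM.

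Alternatives set beforehand were pseudocounts of 0.1 and 10 TPM, log2 of the mean TPM over cells, no filter on cells, at least 2000 genes per cell, cells with a Cd3 or Cd4 transcript, and cells weighted to a like distribution of genes per cell in bins of 500 genes. Others rescaled TPM without mitochondrial, ribosomal protein and the 10 highest genes, subtracted the median of all genes, or set the 25% limit to 0 or 50%. Shares were also counted above 0 and above 10 TPM. A difference that moved by 0.585 (1.5-fold) or more was called moved.

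The method was tested on simulated data, with 2 groups drawn from the 95 Th1 eGFP-positive control cells over 8630 genes and compared after known changes. Each gene was drawn from the cells on its own, which removes links between genes and differences in genes per cell. Genes raised 4-fold had a median true difference of 1.42 and a recovered one of 1.50, and genes raised 2-fold 0.69 and 0.77. Genes lowered to 0.5-fold gave −0.77 and −0.71. Directions were right for 98% of genes at 2-fold and for 100% at 4-fold. Of 200 unchanged lists of random genes, 7% lay outside the central 95% of percentiles. That share need not hold for lists of genes that move together or for plates that differ in genes per cell. Computations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.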

Results

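Naive CD4 T cells of spleen and lymph nodes were sorted from mice whose Il23r locus, which encodes the receptor subunit for interleukin 23, carries an eGFP reporter. They were cultured for 4 days with IL-12, IL-21 and IL-23 (called the Th1 condition) or with IL-1β, IL-6 and IL-23 (the pathogenic Th17 condition). Viable CD4 cells were then sorted by eGFP into 96-well plates. After the filter, 95 control and 95 KO cells remained in the Th1 eGFP-positive gate and 95 and 91 in the Th1 eGFP-negative gate. In the Th17 condition 94 and 95 cells remained in the eGFP-positive gate and 95 and 95 in the eGFP-negative gate. The median number of genes per cell was 6843 in control and 6358 in KO cells of the Th1 eGFP-positive gate, and 6594 and 5637 in the Th1 eGFP-negative gate. In the Th17 condition it was 6998 and 6647 in the eGFP-positive gate and 6214 and 5751 in the eGFP-negative gate. No replicates are labelled in any group, and the plate of a group cannot be told apart from the group. All differences are on the log2(TPM + 1) scale, and shares stand with exact 95% intervals that cover the counting error of cells alone.

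The targeted gene was examined first. Il23r (GRCm38 chromosome 6, 67422932 to 67491855) was above 1 TPM in 95.8% (89.6 to 98.8%) of control and 86.3% (77.7 to 92.5%) of KO cells in the Th1 eGFP-positive gate. In the Th1 eGFP-negative gate the shares were 20.0% (12.5 to 29.5%) and 17.6% (10.4 to 27.0%). Th17 cells had Il23r in 85.1% (76.3 to 91.6%) of control and 88.4% (80.2 to 94.1%) of KO cells of the eGFP-positive gate, and in 8.42% (3.71 to 15.9%) and 12.6% (6.70 to 21.0%) of the eGFP-negative gate. Mean Il23r was 75.6 and 52.9 TPM in Th1 eGFP-positive control and KO cells, and 55.8 and 42.3 TPM in their Th17 counterparts. The reporter transcript was present in 76.8% (67.1 to 84.9%) and 73.7% (63.6 to 82.2%) of Th1 eGFP-positive control and KO cells, and in 54.3% (43.7 to 64.6%) and 69.5% (59.2 to 78.5%) of Th17 ones. In the eGFP-negative gates it was seen in 4.21% and 11.0% of Th1 and 2.11% and 2.11% of Th17 control and KO cells. Both transcripts thus went with the gate in each condition and genotype. The labels do not say which part of Il23r the reporter allele lacks, so its transcript in KO cells checks the gate and not the genotype.

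**Figure D1:**
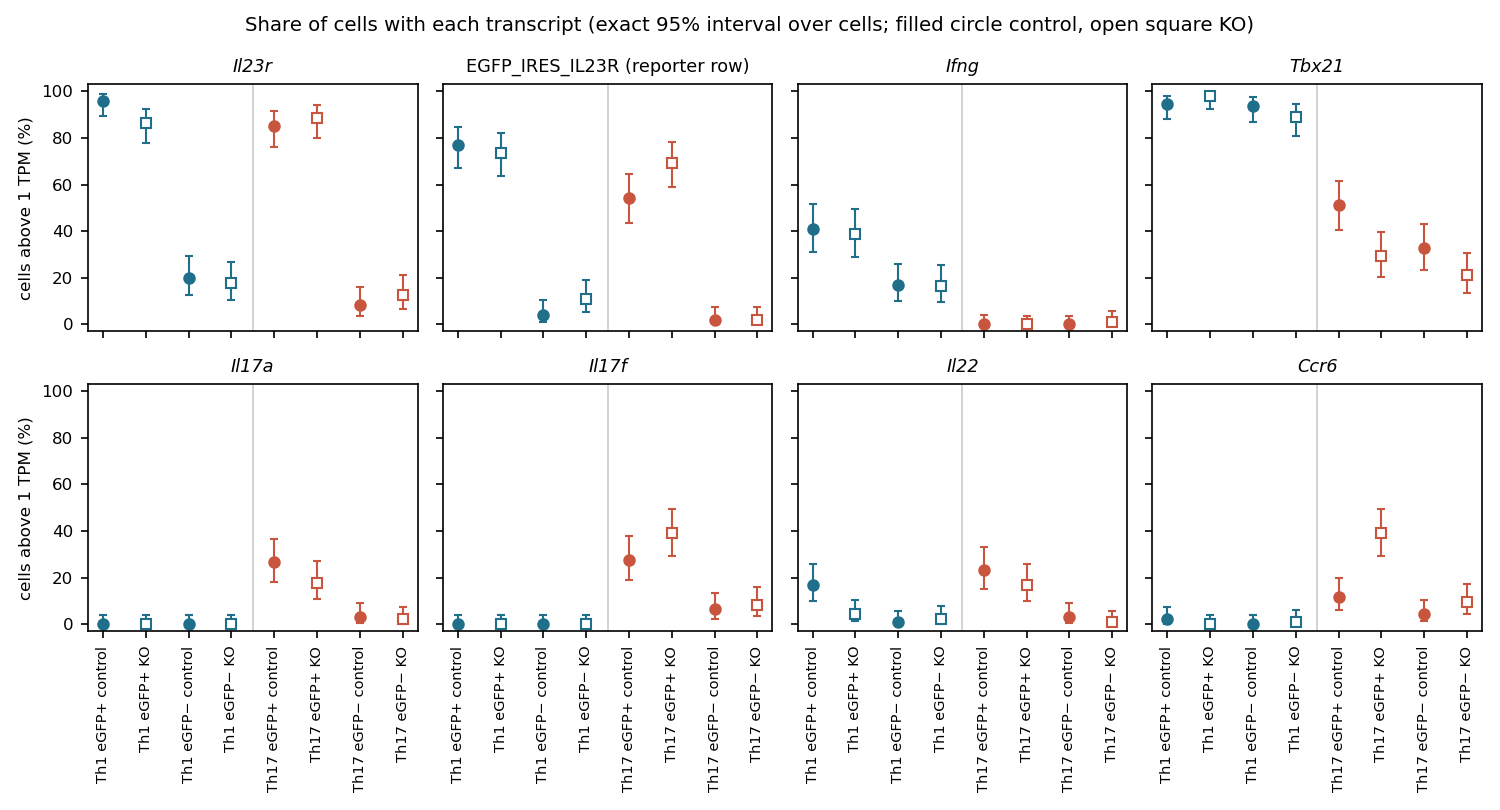
Share of cells above 1 TPM (%) for 8 transcripts in the 8 groups, with filled circles for control cells, open squares for KO cells, blue for Th1, red for Th17 and bars for exact 95% intervals over cells. Ifng reached 41.1% in Th1 eGFP-positive control cells, and Il17a was seen in Th17 groups alone, in up to 26.6% of cells.

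The first comparison asks how the culture conditions differ, Th17 minus Th1, in 4 pairs of plates matched on gate and genotype. Ifng (GRCm38 chromosome 10, 118441046 to 118445894), the lead cytokine of Th1 cells, was expressed in 41.1% (31.1 to 51.6%) of control and 38.9% (29.1 to 49.5%) of KO cells of the Th1 eGFP-positive gate, with means of 725 and 637 TPM. In the Th1 eGFP-negative gate the shares were 16.8% and 16.5%. Of the Th17 groups, 3 had no cell with Ifng, which allows up to 3.19% in the eGFP-positive control group, and the eGFP-negative KO group had 1.05%. Il17a (GRCm38 chromosome 1, 20730905 to 20734496) and its neighbour Il17f, cytokines of Th17 cells, were at 0 in all 4 Th1 groups, with an upper limit of 3.16% in eGFP-positive control cells. In Th17 eGFP-positive cells Il17a was found in 26.6% (18.0 to 36.7%) of control and 17.9% (10.8 to 27.1%) of KO cells, and Il17f in 27.7% (18.9 to 37.9%) and 38.9% (29.1 to 49.5%). Tbx21 (GRCm38 chromosome 11, 97098007 to 97115331), which encodes the Th1 transcription factor T-bet, was present in 94.7% (88.1 to 98.3%) of Th1 and 51.1% (40.5 to 61.5%) of Th17 eGFP-positive control cells. No cell held both Ifng and Il17a.

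Among genes with 1 direction in the 4 pairs, those lowest in Th17 cells included Plac8, with differences of −6.45 and −7.41 in eGFP-positive control and KO cells and −5.52 and −4.59 in eGFP-negative ones. Tbx21 ranged from −5.37 to −4.12, and its mean was 6.74 (SD 2.09) in Th1 and 2.62 (SD 2.83) in Th17 eGFP-positive control cells. Irf8, a transcription factor of the interferon regulatory family, ranged from −4.74 to −2.79, and Nkg7, a protein of cytotoxic granules, from −5.42 to −2.65. The surface protein gene Ly6c1, which has a near copy in Ly6c2 and is uncertain for that reason, ranged from −4.67 to −2.95. Crabp2, a carrier of retinoic acid, and Furin, a protease that cleaves proproteins, differed by −3.21 and −2.41 in eGFP-positive control cells. In that pair Gadd45g was at −2.43, the interferon-induced Ifitm3 at −2.22 and the NADPH oxidase subunit Ncf1 at −2.58. Higher in Th17 cells were the chemokine receptor Ccr4, from 2.31 to 3.24, and Gata3, the transcription factor of Th2 cells, from 1.84 to 2.41. Il1r2, a decoy receptor for IL-1, was higher by 1.28 in eGFP-positive control and 3.56 in eGFP-positive KO cells. Ifngr2, Ntrk3, Lad1, Inhba, Evl and Tmem50b were higher by 0.94 (Tmem50b) or more in each pair.

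**Figure D2:**
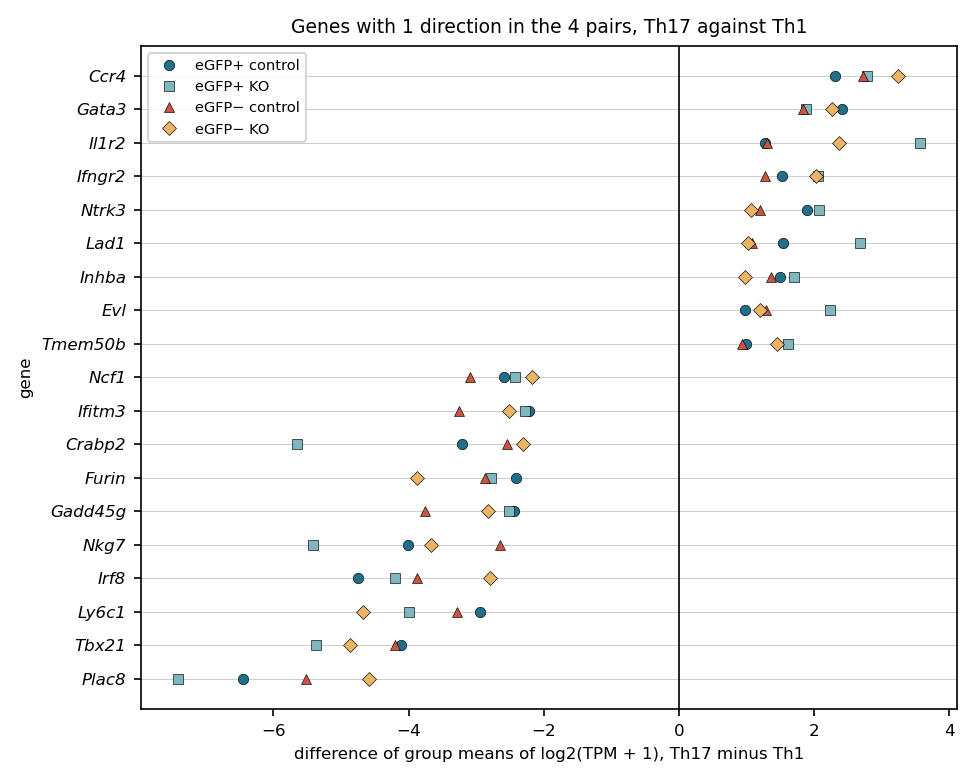
Difference of group means of log2(TPM + 1), Th17 minus Th1, on the horizontal axis for 19 genes with 1 direction in the 4 pairs, with a marker for each pair. Plac8 lies lowest, at −7.41 in eGFP-positive KO cells, and Il1r2 reaches 3.56 there.

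By lists, the Th1 programme was lower in Th17 cells in all 4 pairs, and the Th17 programme showed less contrast. The Th1 list median relative to all genes was −0.98 and −1.51 in eGFP-positive control and KO cells and −0.99 and −1.00 in eGFP-negative ones, each at percentile 0. In eGFP-positive control cells Ifng differed by −3.64 and Il18r1, a receptor for IL-18, by −2.24. The Th17 list lay at 0.40 (percentile 100) in eGFP-positive control, −0.11 (27.4) in eGFP-positive KO, 0.25 (95.7) in eGFP-negative control and 0.15 (86.8) in eGFP-negative KO cells. In the eGFP-positive KO pair the median before subtraction, −0.09, had another sign than the mean, 0.46. Il17f, Il17a and Batf differed by 2.85, 2.37 and 1.63 in eGFP-positive control cells. Cytotoxic effector genes were lower in Th17 cells, with medians from −1.32 to −0.87, all at percentile 0. Gzmb (granzyme B), Ctsw and the receptor Klrk1 differed by −2.29, −2.10 and −1.33 in eGFP-positive control cells. With genes limited to those in 50% of cells, 3 genes of the cytotoxic list were left in the eGFP-positive KO pair and their median turned to 0.10. Each list median describes the members past the 25% limit, and without that limit 27 of 274 medians moved, 24 of them toward 0 and 3 past it to the other sign. The Th1 programme in eGFP-positive KO cells was then −0.76 in place of −1.49 before subtraction. The cytotoxic ones were then −0.46, −0.31 and −0.20 before subtraction in the other 3 pairs.

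Th2 genes were higher in the Th17 condition, by 0.82 (percentile 100) and 0.31 (94.3) in eGFP-positive control and KO cells and by 1.36 and 0.83 in eGFP-negative ones, the last at 0.14 before subtraction without the limit on low values. Besides Gata3 and Ccr4, the chemokine receptor Ccr8 differed by 1.22 and Crlf2 by 0.59 in eGFP-positive control cells. Cell cycle genes were lower in 3 pairs, with medians of −0.89, −0.57 and −0.51, and higher in eGFP-negative KO cells, at 0.35. Stmn1, Rrm2, Tk1 and Top2a were at −2.10, −1.90, −1.63 and −1.37 in eGFP-positive control cells. Interferon response genes were lower in Th17 control cells, at −0.55 (percentile 0) and −0.72 (0), with Gbp2 at −1.94, Zbp1 at −1.66 and Gbp3 at −1.43 in the eGFP-positive pair against Xaf1 at 1.13. In KO cells the same list lay at 0.20 (99.5) and −0.06 (36.7), and with genes in 50% of cells the eGFP-positive value turned from 0.226 to −0.619 before subtraction. The median of all genes differed by 0.09, 0.02, −0.14 and −0.00 in the 4 pairs, in the order used here, and gene differences are given without subtracting it. Between any 2 of the 4 pairs the differences had a Pearson's r across genes of 0.25 to 0.52 for the 6 combinations, where genes are not independent replicates.

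**Figure D3:**
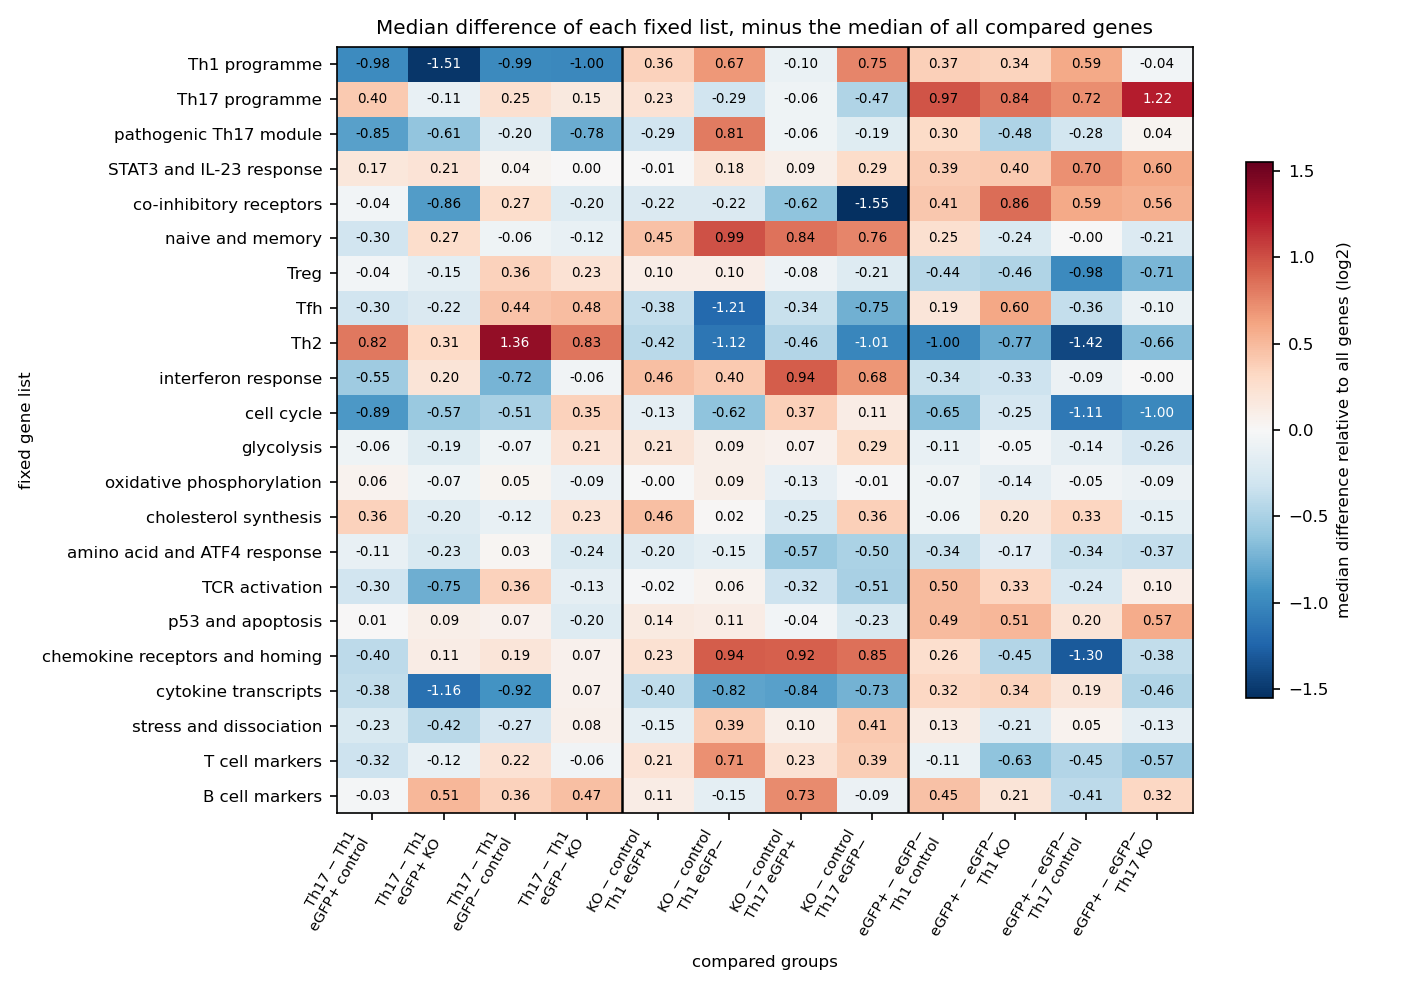
Colour and number give the median difference of each fixed list relative to the median of all compared genes (log2) for 22 lists with at least 5 compared genes in each of the 12 comparisons. The Th1 programme is negative in the 4 Th17 minus Th1 columns, and naive and memory genes lie from 0.45 to 0.99 in the 4 KO minus control columns.

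The second comparison asks what differs in cells whose Il23r alleles both carry the reporter, KO minus control, in 4 pairs of plates. Among the highest genes with 1 direction in all pairs were Ms4a4b, Susd3, Icos and Igfbp4. Ms4a4b, a membrane protein gene of T cells with close relatives in its family, was higher by 3.28 and 4.92 in Th1 eGFP-positive and eGFP-negative cells and by 2.35 and 4.56 in Th17 ones. It was found in 44.2% (34.0 to 54.8%) of control and 76.8% (67.1 to 84.9%) of KO cells of the Th1 eGFP-positive gate. Icos, a co-stimulatory receptor, was higher by 0.92 to 2.10. The 5 lowest were Stra6, Gata3, Ccr8, Amd2 and Il21. Stra6, a receptor for retinol-binding protein, ranged from −3.29 to −2.40 (in Th1 eGFP-negative cells −3.00, and −2.16 once genes per cell were matched), Gata3 from −3.38 to −2.17 and Ccr8 from −3.21 to −1.83. Il21, a cytokine gene next to Il2, was lower by a narrow range, −1.60 to −1.29. Amd2 has a near-identical copy in Amd1, so its values are uncertain. Control and KO cells of the Th1 condition came from 1 mouse each, and fewer genes were listed per KO cell in every pair, which moves with all of these differences.

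**Figure D4:**
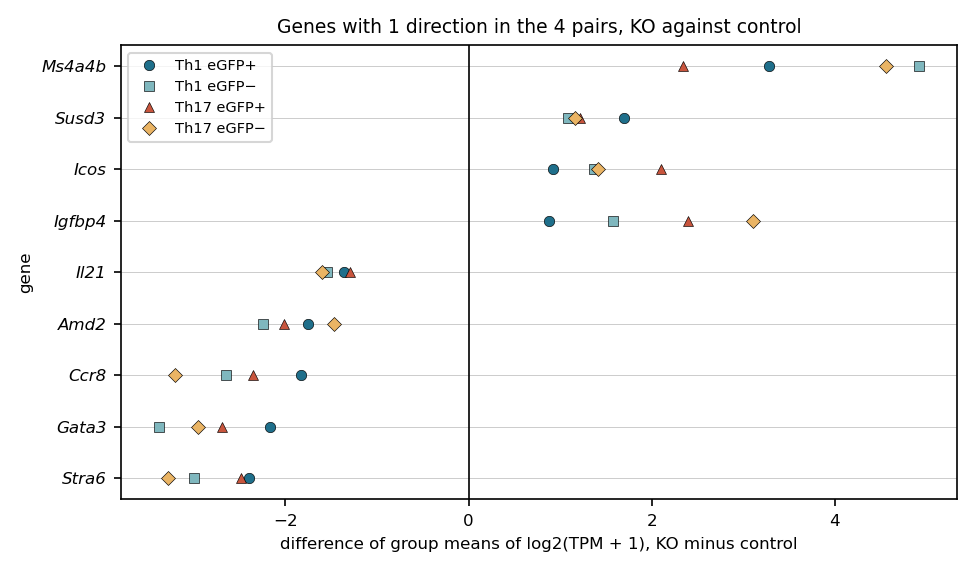
Difference of group means of log2(TPM + 1), KO minus control, on the horizontal axis for 9 genes with 1 direction in the 4 pairs, with a marker for each pair. Ms4a4b lies highest, at 4.92 in Th1 eGFP-negative cells, and Gata3 lowest, at −3.38 in the same cells.

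In Th1 eGFP-positive cells Ifng differed between genotypes by −0.42 and its regulator Tbx21 by −0.00, and the shares of both had overlapping intervals. Il22, a cytokine acting on epithelia, was found in 16.8% (9.94 to 25.9%) of control and 4.21% (1.16 to 10.4%) of KO cells, and Il2, the T cell growth factor, in 34.7% (25.3 to 45.2%) and 11.6% (5.92 to 19.8%). Outside the genes already named, the highest included Serpinb5 (1.75), Spata13 (1.43), the co-stimulatory receptor Tnfrsf9 (1.39), the lymph node homing receptor Ccr7 (1.39), Plac8 (1.36), H2-Q9 (1.25) and Usp18 (1.21). H2-Q9 shares reads with other members of its family and is uncertain. The lowest were Inhba, which encodes an activin subunit (−2.71), S100a6 (−2.43), Mtmr7 (−1.91), Creld2 (−1.73), Slc2a6 (−1.72) and Slc15a3 (−1.67). Creld2 was at −1.06 once genes per cell were matched.

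Of the lists, genes of naive and memory cells were higher in Th1 eGFP-positive KO cells, at 0.45 (percentile 100), with Ccr7 and Igfbp4 (0.88) above and the transcription factor Bach2 (−0.74) below control. Interferon response genes were higher, at 0.46 (100), with Usp18 and the GTPase Irgm1 (1.12). Irf7 was lower, at −0.60, but at 0.37 as log2 of the mean TPM. The Th1 programme lay at 0.36 (100), with Fasl (0.84), Il18r1 (0.75) and Ifngr1 (0.75) higher and the chemokine Ccl4 (−1.07) lower. Its median before subtraction was 0.227, and as low as 0.0082 over the alternatives. The Th17 programme lay at 0.23 (96.8), and its mean before subtraction, −0.18, had another sign. Th2 genes were lower, at −0.42 (0.670), with Gata3, Ccr8, Nfil3 (−0.64) and Ccr4 (−0.46). Cytokine transcripts were lower, at −0.40 (0.0800), with Il2 (−1.43), Il21 and Lif (−1.16) below and Lta (1.05) above control. The median of all genes differed by −0.13.

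In Th1 eGFP-negative cells the differences between genotypes were wider. Serpinb5 (2.62), Lysmd2 (2.53), Tesc (2.49) and Rnf187 (2.25) were higher in KO cells. Tnp2 (−3.28), the Th2 cytokine Il4 (−2.96) and the stress-induced factor Atf3 (−2.85, and −2.23 once genes per cell were matched) were lower. Gzmb was found in 54.7% (44.2 to 65.0%) of control and 74.7% (64.5 to 83.2%) of KO cells. The lists of naive and memory genes (0.99, percentile 100), homing genes (0.94, 100), the Th1 programme (0.67, 100) and cytotoxic effectors (1.46, 100) were higher. Th2 genes (−1.12, 0) and follicular helper genes (−1.21, 0) were lower, but matching genes per cell moved the latter median from −1.535 to −0.671 before subtraction. Without the limit on low values the medians of the homing, cytotoxic, Th2 and follicular helper lists were 0.0055, 0.24, −0.40 and −0.12 before subtraction. That of the Th1 programme was 0.34 before subtraction, and as low as 0.029 over the alternatives. The stress and dissociation list, a sign of handling, was higher in KO cells relative to all genes, at 0.39 (97.9). Before subtraction its median was 0.06 and its mean, −0.24, had another sign. The median of all genes differed by −0.33. Cell cycle genes lay at −0.62 (0.0100), a direction that turned once genes per cell were matched, from −0.95 to 0.43 before subtraction.

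In Th17 eGFP-positive cells the genotypes differed in Il17a and Ccr6, among others. Mean Il17a was 622 TPM in control and 78.1 TPM in KO cells, although the intervals of its shares overlapped. Mean Il17f was 859 and 393 TPM, which a few high cells can set, but its share was 27.7% (18.9 to 37.9%) in control and 38.9% (29.1 to 49.5%) in KO cells and its log2 difference 0.22. Ccr6, a chemokine receptor of Th17 cells, was found in 11.7% (5.99 to 20.0%) of control and 38.9% (29.1 to 49.5%) of KO cells. Tbx21 was seen in 51.1% (40.5 to 61.5%) and 29.5% (20.6 to 39.7%), a difference of −1.26. Among the highest genes in KO cells, besides Igfbp4 (2.40) and Icos, were Lsp1 (2.30), Ltb, which encodes lymphotoxin beta (2.24), Il1r2 (2.21), Timd2 (2.12), Tmem160 (2.08) and Ccr7 (2.06). The lowest were Dusp6, a phosphatase of MAP kinases (−3.17), Tnfaip3, an inhibitor of NF-κB signalling (−2.63), Inhba (−2.50), Mrps28 (−2.45), Calcrl (−2.44), the cytokine Il24 (−2.37) and Cystm1 (−2.36).

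Interferon response genes were higher in Th17 eGFP-positive KO cells, at 0.94 (percentile 100), with Isg20 (1.58), Irgm1 (1.22), Gbp3 (1.09) and Usp18 (1.05). Genes of naive and memory cells lay at 0.84 (100), with Id3 at 1.24, and homing genes at 0.92 (100), with Ccr6 at 1.63 and Ccr8 at −2.36, but without the limit on low values the homing median was 0.039 before subtraction. B cell markers were higher as well, at 0.73 (99.9), and genes of T cell receptor activation lower, at −0.32 (0.520). Co-inhibitory receptors were lower, at −0.62 (0.0500), with Tigit (−1.81), Btla (−1.58), Cd200 (−1.49) and Lag3 (−1.04). Cytokine transcripts were lower, at −0.84 (0), with Il24, Lif (−1.40), Il21 and Il17a (−1.03) below and Ltb above control, and at −0.40 before subtraction without that limit. The Th17 programme stood near the median of all genes, at −0.06 (44.9), with Ccr6 above and the transcription factor Irf4 (−1.38) below control. The Th1 programme lay at −0.10 (42.6). The median of all genes differed by −0.19, and 12 of the 95 KO cells against 0 of the 94 control cells had RNR2 above 100000 TPM.

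In Th17 eGFP-negative cells Gzmb was among the highest genes in the KO, with a difference of 3.00 and shares of 26.3% (17.8 to 36.4%) in control and 54.7% (44.2 to 65.0%) in KO cells. Igfbp4 (3.11), the translation factor Eif4e3 (2.48) and the interferon-induced Isg20 (2.43) were also higher. Gpm6b (−2.66) and Izumo1r, the folate receptor 4 of regulatory T cells (−2.63), were lower. Co-inhibitory receptors had the lowest list median of this pair, −1.55 (percentile 0), which was −0.020 before subtraction without the limit on low values. Genes of T cell receptor activation lay at −0.51 (0) and Th2 genes lay at −1.01 (0). Interferon response genes (0.68, 100), naive and memory genes (0.76, 100) and the Th1 programme (0.75, 100) were higher, as was the stress and dissociation list (0.41, 99.2). Before subtraction the median of the Th1 programme was 0.54, and as low as 0.020 over the alternatives. The stress and dissociation list was at 0.20 before subtraction, and its mean, −0.06, had another sign. The Th17 programme was lower, at −0.47 (0.160), but its median before subtraction was 0.04 without the limit on low values. Il2 differed by −0.65 here and by 0.71 as log2 of the mean TPM. The median of all genes differed by −0.21.

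The difference between genotypes was then set side by side in the eGFP gates of each condition, without a test. In Th1 cells the KO difference of Il4 was −0.13 in the eGFP-positive and −2.96 in the eGFP-negative gate, where 48.4% (38.0 to 58.9%) of control and 4.40% (1.21 to 10.9%) of KO cells had it. In the eGFP-positive gate 4.21% of control cells had it, so it could hardly fall there and the gap between gates follows in part from that floor. Tnp2, Fahd2a, Ensa and Nup43 also had a higher KO difference in the eGFP-positive gate, by 2.40, 2.18, 2.18 and 2.11, and Nup43 by 1.25 once genes per cell were matched. Tesc, Rnf187, Gzmb, Lamp1 and Panx1 had a lower one, by −3.09, −2.85, −2.49, −2.45 and −2.44. In Th17 cells the KO difference was higher in the eGFP-positive gate for the histone gene Hist1h1e (2.50), Fam213a (2.42), Acsl3 (2.25), Il4 and H2-Q6 (2.23), and lower for Dusp6 (−2.56), Mrps28 (−2.40), Ms4a4b (−2.21), Tango2 (−2.12) and Plac8 (−1.98). For Il4 in Th17 cells the value was 2.24, and −0.34 as log2 of the mean TPM, and 12.8% of eGFP-positive against 57.9% of eGFP-negative control cells had it. H2-Q6 shares reads with its family and is uncertain, and was at 1.58 with the highest row per symbol.

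The third comparison asks what sets eGFP-positive apart from eGFP-negative cells of 1 culture, in control cells. Il23r (Th1 4.62, Th17 4.31) and the reporter transcript EGFP_IRES_IL23R (Th1 4.09) follow from the sort itself. Timp1, an inhibitor of metalloproteinases, was higher in eGFP-positive cells by 4.26 in Th1 and 4.40 in Th17 cells, and Inhba by 3.20 and 3.34. Il4 was lower by −3.00 and −2.86, and was found in 4.21% (1.16 to 10.4%) of eGFP-positive and 48.4% (38.0 to 58.9%) of eGFP-negative Th1 control cells. Izumo1r was lower by −1.91 and −3.81, and Ubash3a, a negative regulator of T cell receptor signalling, by −1.74 and −2.49. In Th1 cells Ifng was higher by 2.66, with shares of 41.1% and 16.8%, as were the phosphatase Dusp2 (2.71), Phlda3 (2.58), H2-Q10 (2.57, uncertain for shared reads), Atp6v0d2 (2.54) and S100a6 (2.42). Gata3 (−2.15), H2-Q9 (−2.04), Mir703 (−1.84), Ensa (−1.71), Id2 (−1.71), Trp53i11 (−1.69) and Tnp2 (−1.68) were lower. In Th17 cells Lum (3.33), the p53 target Perp (3.31), Ermn (3.07), the growth factor Pdgfa (3.02), Dcxr (3.00), the IL-12 receptor gene Il12rb2 (3.00), which lies beside Il23r, and Smim3 (2.98) were higher. Cyp11a1, which starts steroid synthesis (−2.65), Ltb (−2.62), Treml2 (−2.47), H2-Q9 (−2.40), Gpm6b (−2.33), Ctla2a (−2.29) and Ahcyl2 (−2.26) were lower. With genes per cell matched, Perp, Dcxr and Ltb were nearer to 0 in Th17 cells, at 2.68, 2.25 and −2.02.

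**Figure D5:**
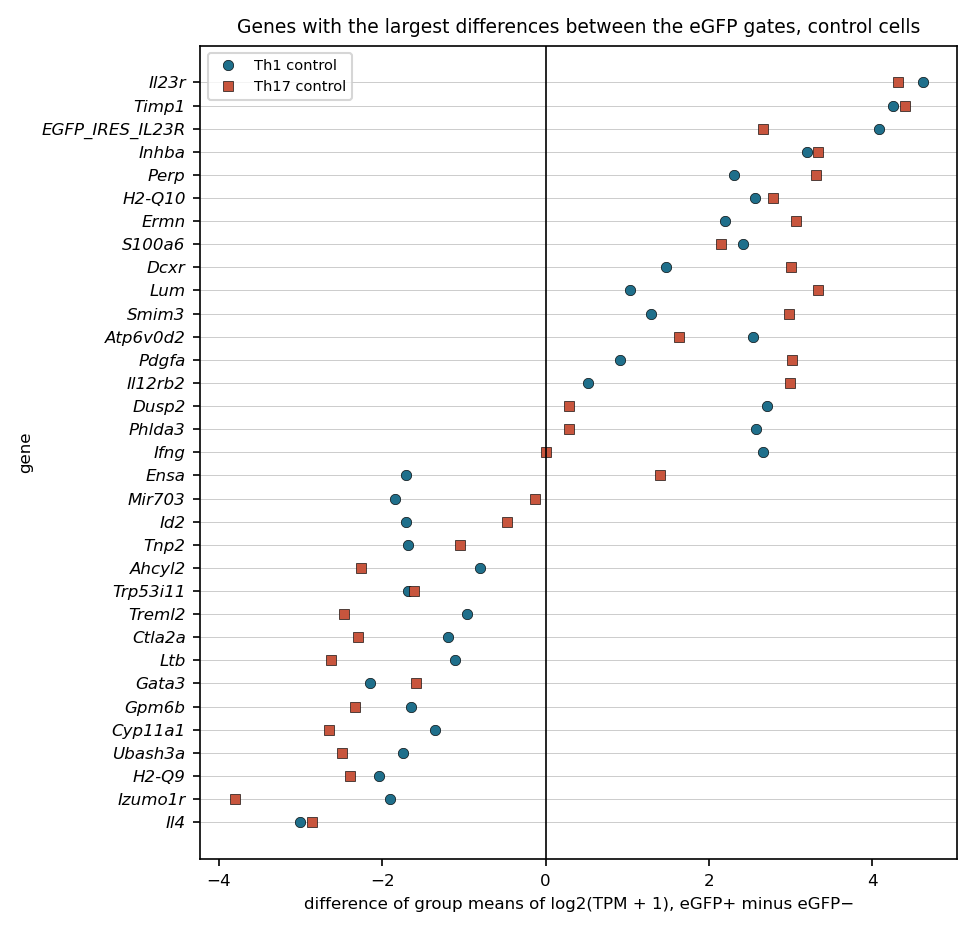
Difference of group means of log2(TPM + 1), eGFP-positive minus eGFP-negative, on the horizontal axis for the genes named between the gates, with circles for Th1 and squares for Th17 control cells. Timp1 and Inhba lie above 3 in both conditions, and Ifng is at 2.66 in Th1 cells.

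The Th17 programme was higher in eGFP-positive cells of both conditions and genotypes. Its median was 0.97 in Th1 control, 0.84 in Th1 KO, 0.72 in Th17 control and 1.22 in Th17 KO cells, all at percentile 100, and Il23r itself is a member. These medians rest on the 9 to 13 members past the 25% limit, and without it they were 0.078, 0.18, 0.12 and 0.093 before subtraction, in place of 1.02, 1.10, 0.99 and 1.51. The polyamine oxidase Smox (1.97 and 2.78) and Rora (1.34 and 2.58) were higher in Th1 and Th17 control cells, and Il17f (2.60) in Th17 ones. The Th1 programme was higher in control cells, at 0.37 (percentile 100) in Th1 and 0.59 (99.7) in Th17 (0.16 before subtraction without the limit), with Il18r1 (2.04), Nkg7 (1.91) and the transcription factor Stat4 (1.17) in Th1 cells. In KO cells it lay at 0.34 (99.6) and −0.04 (40.4). Genes of the STAT3 and IL-23 response were higher, at 0.70 (100) in Th17 control cells, where the signalling inhibitor Socs3 differed by 2.52. They were also higher in Th17 KO (0.60, 100), Th1 control (0.39, 99.8) and Th1 KO cells (0.40, 99.6). In KO minus control this list lay at −0.01 (45.0) and 0.18 (89.6) in Th1 eGFP-positive and eGFP-negative cells. In the Th17 condition it lay at 0.09 (87.2) and 0.29 (98.1), so relative to all genes its median was at or above −0.01. Before subtraction its medians were −0.14 and −0.15 in Th1 eGFP-positive and eGFP-negative cells, and −0.10 and 0.07 in Th17 ones. Its means before subtraction were negative in each pair, from −0.22 to −0.04.

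Th2 genes were lower in the eGFP-positive gate, with medians from −1.42 in Th17 control to −0.66 in Th17 KO cells. Regulatory T cell genes were lower too, at −0.44 (percentile 0.0500) in Th1 and −0.98 (0) in Th17 control cells, with Gpr83 (−1.42), Tnfrsf4 (−1.09) and Tnfrsf18 (−0.96) in the latter. Foxp3 itself was seen in 1.05% (0.0267 to 5.73%) of eGFP-positive and 10.5% (5.16 to 18.5%) of eGFP-negative Th1 control cells. Cell cycle genes lay at −0.65 (0) in Th1 and −1.11 (0) in Th17 control cells, with the replication factor Mcm5 at −1.58 and −1.84. Hmgb2 (−1.30), Mcm3 (−1.09) and Mcm7 (−1.02) were lower in Th1 cells, and Stmn1 (−1.87), Tk1 (−1.70) and Mcm7 (−1.38) in Th17 cells, where matching genes per cell put these 3 at −2.61, −2.285 and −2.01. Homing genes lay at −1.30 (0) in Th17 control cells, with Ccr8 (−2.17) and Ccr4 (−1.37) lower and S1pr1 (2.33) higher, but their median before subtraction was 0.08 without the limit on low values. The median of all genes differed by 0.04 in Th1 control, 0.25 in Th1 KO, 0.27 in Th17 control and 0.30 in Th17 KO cells. KO cells carry the reporter on both alleles, so the gates need not hold like cells in the 2 genotypes.

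Markers of T cells and of other cell types were looked at last. Cd3e was found in 98.9% to 100% and Cd4 in 98.9% to 100% of cells per group. Cd8a, of CD8 T cells, was highest in Th17 eGFP-positive KO cells, at 9.47% (4.42 to 17.2%). The other of the 2 CD8 markers on the list was more frequent and passed the 25% limit in most comparisons. The low share of Cd8a thus does not hold for both. The B cell gene Cd79a reached 7.37% at most across groups, and the myeloid gene Lyz2 was seen in Th17 eGFP-positive control cells alone, at 1.06%. Other B cell markers were more frequent, and 6 of the 14 on the list passed the 25% limit in each comparison. No gene of the lists for innate-like or erythroid cells passed the 25% limit in any comparison. The CD8 T cell and myeloid lists had at most 1 compared gene each and were given no median.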

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

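The ratio between the gates, the number of animals, the size among cells with cell cycle genes, and the ratios of Il17a with unequal numbers of cells left out, over resampled cells and among cells with it were tests chosen only after the result was seen.

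The well numbered 85 listed the most genes on each of the 8 plates, 9194 to 10840 against at most 8763 in any other well. A deeper library of a single cell would list few T cell receptor beta variable (Trbv) genes, since a T cell uses few of them. The lowest number of Trbv genes above 10 TPM in this well was 10, against a highest number of 7 in the other wells, which argues against a single cell. More than 1 cell in the well may account for it, since the well had more than 2 such genes on 8 plates. Whether the well was filled on purpose is not given in the sources used here, and no biological explanation was tested.

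KO minus control had a set of genes with 1 direction in all 4 pairs of plates, Gata3 and Ccr8 lower and Ms4a4b and Icos higher among them. Naive cells that were never activated among the KO wells would raise genes of naive and memory cells, which were higher in all 4 pairs (0.45 to 0.99), and lower those of T cell receptor activation, which lay at −0.32 and −0.51 in Th17 but at −0.02 and 0.06 in Th1 cells. They would also bring less cell cycling, but the cell cycle list lay above or within 0.2 of all genes in 3 pairs. In the other, Th1 eGFP-negative cells, it lay at −0.62 (percentile 0.0100), as such cells would bring about. Its direction turned there once genes per cell were matched. Matching takes weight from cells with few genes, so the turn cannot count against such cells if they list few. Among cells with at least 12 of the 24 cell cycle genes, which never-activated cells would not be, 83.2% of the median size was left. With at least 16 genes 80.4% was left. By pair it was 67.8% in Th1 eGFP-negative, 71.1% in Th1 eGFP-positive, 78.8% in Th17 eGFP-positive and 100.6% in Th17 eGFP-negative cells. In Th1 eGFP-negative cells 43 KO and 73 control cells reached that limit. With at least 6 genes 99.0% was left, but few cells were removed. The genes were picked in the same cells, so noise counts toward this size and it cannot decide on never-activated cells. The naive and memory list was fixed beforehand. Over limits of 6 to 16 genes it was at 0.61 to 0.68 before subtraction in Th1 eGFP-negative cells, against 0.66 in all cells. It was at 0.63 to 0.70 in Th17 eGFP-positive cells, against 0.64, and at 0.51 to 0.67 in Th17 eGFP-negative cells, against 0.55. These values argue against never-activated cells as the whole cause of the list's rise in these 3 pairs. In Th1 eGFP-positive cells the list was at 0.062 to 0.25, against 0.32, so a part of it stayed open in that pair. Loss of the receptor acting only inside cells that carry it stayed open. The median size in eGFP-positive cells was 0.795 times that in eGFP-negative cells, or 0.914 times relative to all genes, but the genes were picked for 1 direction in eGFP-negative cells too, so the ratio decides nothing. Fewer genes detected per cell on the KO plates stayed open. After matching, 59.5% of the median size, 0.25 of 0.42, was left. That size ignores direction and the genes were picked in the same cells, so noise counts toward it and it cannot show what outlasted matching. The animal or culture cannot be told apart from the genotype, since the cell table names 1 animal per genotype.

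Mean Il17a was 7.97 times as high in control as in KO cells of the Th17 eGFP-positive gate. The 5 highest cells held 57.8% of the Il17a TPM of control and 77.4% of that of KO cells. Without them the means were 277 and 18.6 TPM and their ratio was 14.9 (95% interval 1.95 to 90.4 over resampled cells), which argues against a few cells with very high Il17a as the whole cause. Taking 5 cells from each group removes more of the KO cells with Il17a, so the ratio was also 9.52 with 5 control and 3 KO cells left out, a like share of those with Il17a, and 3.55 with the 5 control cells alone left out. Fewer genes detected on the KO plate did not account for it, since the ratio was 9.15 after matching genes per cell. Cells with Il17a were 25 of 94 in control and 17 of 95 in KO, shares whose intervals overlapped and whose ratio was 1.49, and the means among these cells were 2340 and 436 TPM, a ratio of 5.37. The difference could follow from the genotype, the animal or the plate. With 1 plate per group, no test set these apart.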

How the results depend on the processing

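Of 6456 gene differences recomputed under the alternatives, 5684 stayed within 1.5-fold of the reported value, 769 moved by more and 3 of at least 1.5-fold turned sign. Of 3833 list medians 3756 stayed, 72 moved and 5 of at least 1.5-fold turned, and of 1104 shares 1071 stayed within their interval and 33 moved. Counting values below 1.5-fold as well, where a small move is enough, 99 gene differences and 233 list medians had another sign than the reported one, 41 of the medians after subtracting the median of all genes. Among gene differences the choice of scale moved most: with a pseudocount of 0.1 TPM 246 gene differences moved, all away from 0, with 10 TPM 249 moved, all toward 0, and with log2 of the mean TPM 258 moved, 106 away from 0 and 152 toward it. Among list medians the absence of a limit on low values moved most, 24 toward 0 and 3 past it, and among shares the limit of 10 TPM, 27. No filter on cells, at least 2000 genes per cell, rescaling, subtracting the median of all genes, leaving out cells with high RNR2 and leaving out well 85 moved no gene difference and no list median, and the limit to cells with Cd3 or Cd4 removed no cell. Some of these settings had little room to move a value. The median of all genes was −0.33 at its widest, short of the 1.5-fold limit. At least 2000 genes per cell left 94 of the 95 Th1 eGFP-positive control cells and removed no other cell. Leaving out well 85 removed a single cell from each group. That these settings moved no difference or median says little, although they count toward the values that stayed. Values here are medians before subtraction. The Th1 programme kept its sign for Th17 minus Th1 under all 14 alternatives, from −1.20 to −0.49 in eGFP-positive control and from −1.85 to −0.76 in eGFP-positive KO cells, as the Th17 programme did between the gates. For medians nearer to 0 the sign was kept less often, as for the Th17 programme of Th17 minus Th1 in eGFP-positive KO cells (12 of 14) and the Th1 programme between the gates of Th17 KO cells (10 of 14). The Th17 programme between the gates was 1.89 in Th1 KO, 1.83 in Th17 control and 2.46 in Th17 KO cells with a pseudocount of 0.1 TPM. With 10 TPM it was 0.42 in Th1 control, 0.44 in Th1 KO and 0.63 in Th17 KO cells, and the Th1 programme, Th17 minus Th1, was −0.87 in eGFP-positive KO cells. Without a limit on low values, which adds genes at or near 0, the Th17 programme between the gates was 0.078 in Th1 control, 0.18 in Th1 KO, 0.12 in Th17 control and 0.093 in Th17 KO cells. The Th1 programme was then −0.76 in Th17 minus Th1 for eGFP-positive KO cells and 0.16 between the gates of Th17 control cells. In that setting 3 medians of at least 1.5-fold turned sign: cytokine transcripts, Th17 minus Th1, to 0.11 in eGFP-negative control cells, the Th17 programme, KO minus control, to 0.035 in Th17 eGFP-negative cells, and homing genes to 0.077 between the gates of Th17 control cells. With genes in 50% of cells, which leaves fewer genes, the Th17 programme was −1.52 over 5 genes for KO minus control in Th17 eGFP-negative cells and 1.60 over 8 genes between the gates of Th17 control cells, and the cytotoxic list turned to 0.096 over 3 genes for Th17 minus Th1 in eGFP-positive KO cells. That limit left too few genes for 3 of the 274 list medians. Matching genes per cell turned the cell cycle list of KO minus control in Th1 eGFP-negative cells from −0.95 to 0.43, put it at 0.41 in place of −0.26 in Th1 eGFP-positive cells, and made it lower between the gates, at −0.99 in place of 0.00 in Th1 KO, −1.55 in place of −0.84 in Th17 control and −1.80 in place of −0.71 in Th17 KO cells, and the cause was not tested. It moved 14 gene differences, 9 toward 0 and 5 away from it. As log2 of the mean TPM, which a few high cells can set, the signs turned for Il4 in the KO difference between gates of Th17 cells (−0.34), for Il2 in KO minus control of Th17 eGFP-negative cells (0.71) and for Irf7 in KO minus control of Th1 eGFP-positive cells (0.37), and the cause was not tested. With the highest row per symbol, H2-Q10 between the gates of Th1 control cells was 1.98 in place of 2.57. Without well 85, the shares of Ccr6 in Th1 eGFP-negative KO cells and of Il22 in Th1 eGFP-negative control and Th17 eGFP-negative KO cells were 0, since their single positive cell was that well. TPM keeps no depth, so shares could not be compared at equal depth, and groups with fewer genes per cell can have lower shares for that reason alone. No paired analysis was possible because the numbers in the labels name wells of a plate and no result comes from a test.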

Other observations

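Several key genes stood outside the comparisons described so far. Csf2, the cytokine GM-CSF, was found in at most 2.13% of the cells of any group. Il10, an anti-inflammatory cytokine, was seen in 7.37% (3.01 to 14.6%) of Th17 eGFP-negative control cells and in none of the KO cells of that gate, which allows up to 3.16%. Il1r1, a receptor for IL-1, was present in 26.6% (18.0 to 36.7%) of Th17 and 7.37% (3.01 to 14.6%) of Th1 eGFP-positive control cells, and in 1.05% of Th17 eGFP-negative ones. Il21 was found in 80.2% to 97.9% of cells per group, the highest share being that of Th1 eGFP-positive control cells. Il18r1 was found in 67.4% (57.0 to 76.6%) of control and 81.1% (71.7 to 88.4%) of KO cells of the Th1 eGFP-positive gate. Cxcr3, a chemokine receptor of Th1 cells, was found in 64.9% (54.4 to 74.5%) of Th17 and 53.7% (43.1 to 64.0%) of Th1 eGFP-positive control cells, with overlapping intervals. Il12rb2 was found in 97.9% (92.6 to 99.7%) of Th1 and 71.6% (61.4 to 80.4%) of Th17 eGFP-negative control cells. Stat4 was found in 78.9% and 78.7%, Socs3 in 95.8% and 95.7%, and Tnf in 73.7% and 68.1% of Th1 and Th17 eGFP-positive control cells. Prf1 (perforin) and the receptor Cd160 were rare, with at most 7.69% and 4.21% in any group. Il17a and Il17f were both present in 18.1% (10.9 to 27.4%) of control and 14.7% (8.30 to 23.5%) of KO cells of the Th17 eGFP-positive gate, and Ifng and Csf2 were found together in 1.05% of Th1 eGFP-positive control cells and in no other group.

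Genes of the pathogenic Th17 module are a set of Th17 effector genes fixed from textbook knowledge, of which 8 to 10 were compared between the conditions. In eGFP-positive cells they were lower in the Th17 than in the Th1 condition, at −0.85 (percentile 0) in control and −0.61 (0.0700) in KO cells. In eGFP-negative cells they were lower in KO cells, at −0.775 (0.0100). In eGFP-negative control cells they lay at −0.20 (21.1), within the central 95% of random lists. In KO minus control they lay at −0.29 (2.43) in Th1 eGFP-positive and 0.81 (100) in Th1 eGFP-negative cells. In the Th17 condition they lay at −0.06 (51.3) in the eGFP-positive and −0.19 (15.2) in the eGFP-negative gate. Genes of the amino acid and ATF4 response were lower in KO cells of the Th17 condition, at −0.57 (0.0100) in the eGFP-positive and −0.50 (0) in the eGFP-negative gate. Cholesterol synthesis genes were higher in KO cells of the Th1 eGFP-positive gate, at 0.46 (100), and of the Th17 eGFP-negative gate, at 0.36 (99.9), but lay at 0.02 (84.2) in Th1 eGFP-negative and −0.25 (30.7) in Th17 eGFP-positive cells. Genes of T cell receptor activation were higher in eGFP-positive Th1 control cells, at 0.50 (100), and lay at −0.24 (5.10) between the gates of Th17 control cells. Genes of p53 and apoptosis were higher in eGFP-positive cells, from 0.20 in Th17 control to 0.57 in Th17 KO cells, and co-inhibitory receptors from 0.41 to 0.86. The last value is that of Th1 KO cells, whose median before subtraction went from 1.12 to 0.435 once genes per cell were matched and to 0.128 without the limit on low values. Glycolysis and oxidative phosphorylation showed little, with medians from −0.26 to 0.29 and from −0.14 to 0.09 over the 12 comparisons. The stress and dissociation list ranged from −0.42 in Th17 minus Th1 of eGFP-positive KO cells to 0.41 in KO minus control of Th17 eGFP-negative cells. T cell markers were higher in Th1 eGFP-negative KO than control cells, at 0.71 (100). They also lay above all genes in Th17 eGFP-negative (0.39, 99.9), Th17 eGFP-positive (0.23, 99.9) and Th1 eGFP-positive KO cells (0.21, 95.2). The regulatory Th17 module had at most 2 compared genes and was given no percentile.

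The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were at 0 in all 8 groups. Median RNR2 was higher in KO than in control cells of each pair, with the widest gap in the Th17 eGFP-positive gate, 61122 against 31393 TPM. The KO differences of any 2 of the 4 pairs had a Pearson's r across genes of 0.28 to 0.52, and the differences between the gates one of 0.33 to 0.51. No plate was shared by the pairs set against each other, although the KO minus control pairs of the Th1 condition shared their mice.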
